A study of Mus musculus with 16 samples.

How the data were processed

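Small non-coding RNA was sequenced from 8 populations sorted from the bone marrow of wild-type mice, with 2 libraries per population and 16 libraries in all. Per the labels, total RNA was extracted with Trizol, libraries were made with a small RNA kit and selected on a gel for inserts of about snoRNA length, and they were sequenced on an Illumina NovaSeq instrument. The labels name Trimmomatic 0.38, Bowtie2 2.3.4.1 and the GRCm38 mouse genome. They do not state the parameters, the counting program, the annotation or whether strand was used. The deposited values are raw counts of reads per annotated small RNA interval, with no normalization. In each library 89.0% to 93.2% of the values were even, so both mates of a read pair seem to have been counted. Each file lists only intervals with at least 1 read, and an interval missing from a file was taken as 0.

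Of the 1885 intervals, 1 is named by a sequence accession and is treated as the 45S pre-rRNA. The others were matched by chromosome, start and end to GENCODE release M21, which uses GRCm38. Intervals were placed in 11 classes by gene type and name. A snoRNA without an informative name was placed in the C/D or H/ACA class by its sequence boxes and length, or left unclassified. On 102 C/D snoRNAs classed by name, the box rule gave 84 as C/D, 17 as unclassified and 1 as H/ACA. On 46 H/ACA snoRNAs classed by name it gave 41 as H/ACA and 5 as unclassified. Host genes were assigned by position on the same strand. Similar intervals were found with blastn 2.17.0.

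Total counts per library ranged from 8197458 in CMP library 1 to 41799906 in CLP library 2. CPM is the count over the library total, times 1e6, in the Dlk1-Gtl2 sums, the 10 CPM cutoffs and the pooled levels of enriched features. Counting intervals were taken on read pairs, as counts over 2, and cover counting error only, since the reads carry no molecular identifiers.

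Differences were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by population at a minimum count of 10, which left 749 features. Library sizes were scaled by trimmed mean of M values (TMM). All other CPM values, of single features or of the scarce snRNA intervals summed, are over these scaled library sizes. A quasi-likelihood fit with 1 mean per population left 8 residual degrees of freedom, and p values were adjusted by the Benjamini-Hochberg method over the 749 features with a threshold of 0.05. The fit shares the spread of a feature over all populations, although the pairs differed. Among abundant features the SD of the log2 ratio between 2 libraries was 0.0643 in CMP. It was 0.438, 0.526 and 0.525 in GMP, MEP and Erythroid (median absolute deviation 0.174, 0.109 and 0.108, against 0.0432 in CMP). "Rose", "fell", "higher" and "lower" are used for single features past that threshold. Approximate standard errors (SE) are the log2 fold change divided by the square root of the F statistic. The labels do not say whether the 2 libraries of a population came from different mice, so the p values measure the spread between libraries, which may be technical, and 8 populations rather than mice are compared. A feature was called enriched in a population when it passed against the mean of the other 7 populations and both libraries stood above all 14 others, which chance gives for 0.833% of features if single libraries are exchanged and for 12.5% if the libraries of a population always lie together.

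The comparisons, tests, lists, named-feature rule and a first set of alternatives were chosen before the data were examined. The 14 lists were Dlk1-Gtl2 snoRNAs, Snrpn-Ube3a snoRNAs, C/D snoRNAs, H/ACA snoRNAs, scaRNAs, rRNA-processing snoRNAs, snoRNAs hosted by Gas5, by Snhg1, by Rpl13a and by other ribosomal protein genes, spliceosomal snRNAs, housekeeping small RNAs, Dlk1-Gtl2 miRNAs and cell type markers. Lists with at least 3 tested members were tested in 7 comparisons with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists within a comparison. The named features were the 10 largest called rises and 10 largest called falls between progenitors and mature cells with a mean of at least 10 CPM, and 5 and 5 in each other comparison where the libraries of the sides did not overlap. Named as well were the 10 smallest p values in the test over all populations, 3 enriched features per population, 3 features per difference between branches, and measured members of the rRNA-processing, housekeeping and marker lists. Members of other lists given as examples, the snoRNAs of further host genes and the features that differed in all 3 branches were chosen after their values were seen.

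The summed CPM of the Dlk1-Gtl2 snoRNAs and the class shares were compared between 4 progenitor and 4 mature population means with a two-sided exact permutation test over 70 assignments, which cannot give a p below 0.0286. The sum was taken as log2 with 0.5 CPM added, and class shares were adjusted over 11 classes.

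The pipeline was tested on simulated data. Among 200 features given a known change, the progenitor comparison recovered 74.6% at 1.5-fold and 98.5% at 2-fold, with 3.21% of its calls on unchanged features. The comparison of GMP with Myeloid recovered 34.3%, 55.2% and 84.8% at 1.5-fold, 2-fold and 3-fold. Apart from the set change, every simulated library was drawn from the same mean per feature with independent noise. The simulation thus held no other differences among populations and no shift of a whole class between libraries. These rates need not hold for the real counts.

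Alternatives were relative log expression (RLE) size factors, library totals without TMM, no low-count filter, a filter of at least 10 CPM in 2 libraries, DESeq2 1.42.0, snoRNAs and scaRNAs alone, replicate number as a block, each library left out in turn, libraries of a population summed, stage alone over 16 libraries, Erythroid and MEP out of the progenitor contrast, an estimated list correlation, and other scales and averages for the sum and the shares. Chosen after seeing the data were counts halved, miRNAs left out, features with similar copies or overlaps left out, and both CMP libraries summed.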

Results

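The data are small non-coding RNA counts from progenitor and mature blood cells of wild-type mouse bone marrow. The 4 progenitor populations were the common lymphoid progenitor (CLP), the common myeloid progenitor (CMP), the granulocyte-monocyte progenitor (GMP) and the megakaryocyte-erythroid progenitor (MEP). The 4 mature populations were B, T, Myeloid and Erythroid cells. Each population had 2 libraries, and total counts ran from 8197458 to 41799906 per library. The title of the series concerns snoRNAs of the imprinted Dlk1-Gtl2 locus and rRNA modification, and its design text names snoRNA profiles of progenitor and mature cells. All means below are of 2 libraries with the SD, and all adjusted p values for features are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

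C/D snoRNAs, which guide 2'-O-methylation of RNA, held most counts in every library, from 84.3% to 92.2%. The most abundant feature in 15 of 16 libraries was Gm26224, a C/D snoRNA within Gas5 (chromosome 1, 161035394 to 161035473), and in T library 2 it was Snord2. The 45S pre-rRNA interval held 12.1% ± 0.348 of counts in CMP and 4.83% ± 0.147 in T. H/ACA snoRNAs, which guide pseudouridylation, held 0.532% ± 0.0376 in CLP and 0.823% to 1.19% in the other populations. The mitochondrial tRNA share was 0.0345% ± 0.00436 (SD, n = 4 populations) in progenitors and 0.0178% ± 0.00494 in mature cells (exact permutation p = 0.0286, adjusted p = 0.157). The mitochondrial rRNA share was 0.0443% and 0.0241% (exact permutation p = 0.0286, adjusted p = 0.157). Neither passed the threshold over 11 classes, although 0.0286 is the smallest p that 4 against 4 can give, and no other class did (adjusted p 0.393 to 0.600). At this floor the adjusted test could hardly be passed, since several more classes would have to reach 0.0286 together. It thus says little about the mitochondrial shares. The miRNA share differed between libraries of 1 population. It was 1.69% and 0.745% in the GMP libraries, 1.48% and 0.594% in the MEP libraries and 2.02% and 0.796% in the Erythroid libraries. By Spearman correlation of log2 CPM, the nearest library to each library of GMP, MEP and Erythroid was of another population. In the other populations it was the replicate.

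**Figure D1:**
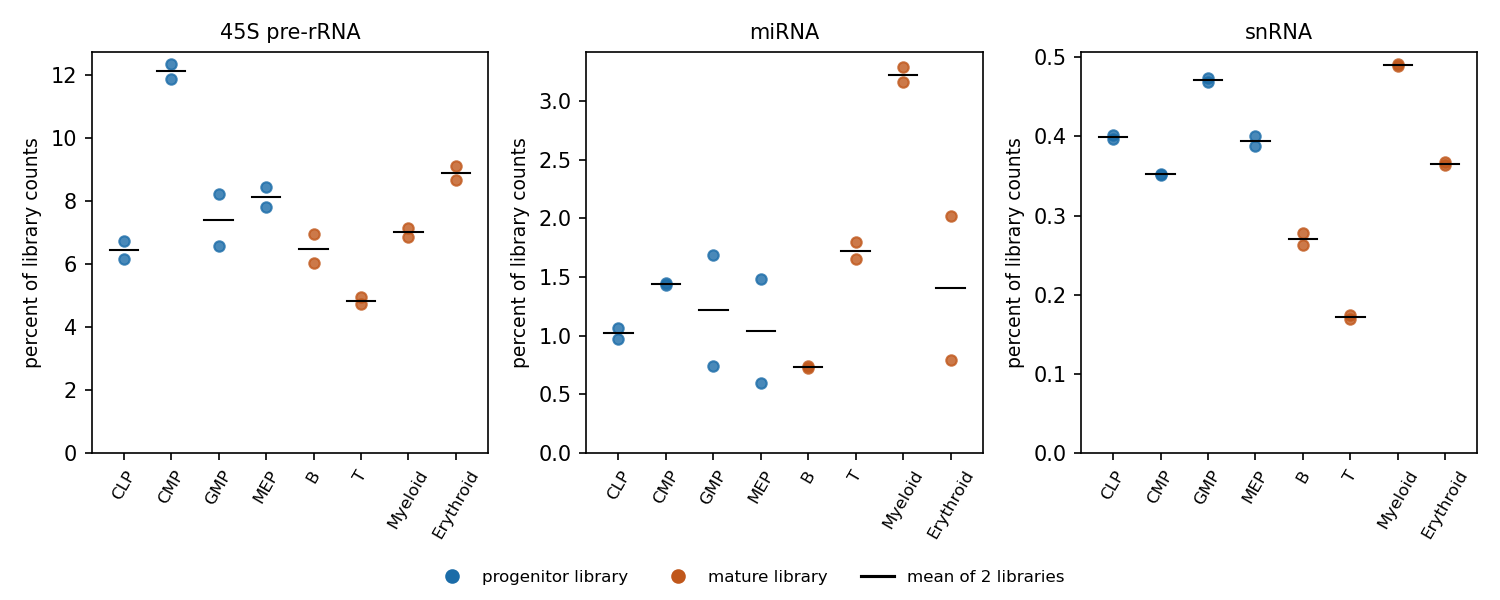
Percent of library counts (vertical axes, from 0) in the 45S pre-rRNA, miRNA and snRNA classes for the 8 populations (horizontal axis). Points are libraries and lines are means of 2; the CMP points are highest for 45S pre-rRNA, and the pairs of GMP, MEP and Erythroid points lie apart for miRNA.

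The Dlk1-Gtl2 snoRNAs, the subject of the series title, were at the edge of detection. Of 23 annotated C/D snoRNAs between Dlk1 and Dio3 on chromosome 12, 8 were listed, with 222 counts over 16 libraries. Their summed level was highest in CMP, at 2.06 ± 0.159 CPM, then MEP at 1.10 ± 0.569 and CLP at 0.772 ± 0.280, while GMP had 0.418 ± 0.00734. The mature populations had 0.589 ± 0.0559 (T), 0.425 ± 0.107 (Erythroid), 0.388 ± 0.00457 (Myeloid) and 0.313 ± 0.265 (B). Gm26922, which RefSeq names AF357355, lies within Rian (109654627 to 109654698) and had the highest count in 1 library, 26 in CMP library 2. The progenitor mean was 1.09 CPM and the mature mean 0.429 (n = 4 populations each), a log2 difference of 0.67 that did not pass the test (two-sided exact permutation p = 0.0857). None of the 8 passed the low-count filter over the 16 libraries. With the libraries of each population summed DQ267100 passed it and did not differ between progenitors and mature cells past the threshold (-0.17, adjusted p = 0.889 by edgeR). The pooled level had a 95% exact interval of 1.42 to 3.01 CPM in CMP and 0.154 to 0.911 in GMP. Of 67 Dlk1-Gtl2 miRNAs 10 were listed and none passed the filter.

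**Figure D2:**
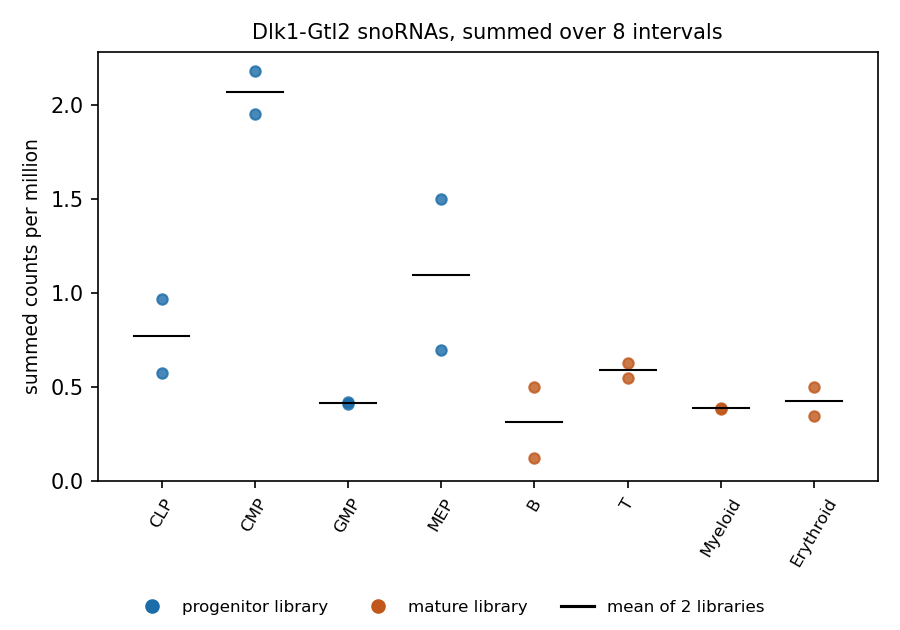
Summed Dlk1-Gtl2 snoRNA level in CPM of library total (vertical axis, from 0) for the 8 populations (horizontal axis). Points are libraries and lines are means of 2; both CMP libraries, at 1.95 and 2.18, stand above the other 14.

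Most tested features varied among the 8 populations, 458 of 749. The 10 smallest p values included abundant C/D snoRNAs that were highest in lymphoid cells. Snord57, within Nop56 on chromosome 2, had 13240 ± 687 TMM-scaled CPM in T and 8915 ± 5.86 in B, against 4520 ± 47.8 to 5586 ± 133 elsewhere (adjusted p = 2.81e-09 by edgeR). Snord68 had 105000 ± 6250 in T and 81360 ± 2490 in B, and at most 52110 ± 2130 in the other populations. Snord49a had 165900 ± 5000 in T and 165000 ± 9470 in B, and at most 88390 ± 3950 elsewhere. Snord90 and Snord2 were also highest in T, at 2304 ± 97.0 and 201800 ± 13100. Snord71 was at 1207 to 1391 in the progenitors and at 2012 to 2900 in the mature cells. Gm25878, a snoRNA within Zfas1, was highest in GMP at 19300 ± 528 and lowest in T at 8347 ± 447. Gm47281 and Gm47276 lie inside annotated 5S rRNA genes, with 73 similar annotated copies each, and were highest in CMP at 780 ± 24.5 and 822 ± 32.8.

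Between progenitors and mature cells, 200 features were higher in progenitors and 173 lower. Among features with a mean of at least 10 CPM, the largest rise was in Snora43 (ENSMUSG00000097052, chromosome 2, 26637847 to 26637985), an H/ACA snoRNA, by 2.11 ± 0.071 (log2 ± SE, adjusted p = 2.13e-09 by edgeR). It had 590 ± 14.6 TMM-scaled CPM in MEP, 301 ± 32.8 in GMP and 190 ± 1.86 in CLP, and 24.1 ± 2.03 in T. CMP, at 67.7 ± 4.32, lay below Myeloid at 91.4 ± 0.275. The mitochondrial methionine tRNA mt-Tm rose by 1.43 ± 0.080 and the glycine tRNA mt-Tg by 1.15 ± 0.089, and 15 of 21 tested mitochondrial tRNAs were higher in progenitors and none lower, of which 2 passed with populations as units. Mir451a/Mir451b, a miRNA of red cell development, rose by 1.14 ± 0.14, with 152 ± 39.7 CPM in MEP, 147 ± 46.9 in Erythroid and 12.1 ± 0.352 in B. The other largest rises at that mean were in Gm27773 (1.59), Gm27656 (1.37), Gm44456 (1.08), n-TStga1 (1.05), and the snRNA intervals Gm25202 (1.05) and Gm25813 (1.04).

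The 10 largest falls at a mean of at least 10 CPM were all in miRNAs. Mir139 (chromosome 7) fell by 2.41 on the log2 scale (SE 0.27, adjusted p = 2.25e-05 by edgeR) and had 22.7 ± 2.49 to 40.5 ± 3.38 CPM in progenitors and 362 ± 27.7 in Myeloid. Mir150, a miRNA of mature lymphocytes, fell by 2.08 (SE 0.24) and had 272 ± 18.2 CPM in T. Mir142, expressed across blood cells, fell by 1.85 and the overlapping Mir142b by 1.81. Mir22, Mir532, Mir342, Mir340, Mir146 and Mir16-2 fell by 1.54, 1.52, 1.38, 1.30, 1.29 and 1.21. Among all 262 tested miRNAs 84 were lower in progenitors and 31 higher. In the GMP, MEP and Erythroid pairs the median miRNA differed between libraries of 1 population by 1.10, 1.27 and 1.28 (log2). Libraries were selected for inserts of about snoRNA length, and whether miRNA recovery differed between progenitors and mature cells was not tested.

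**Figure D3:**
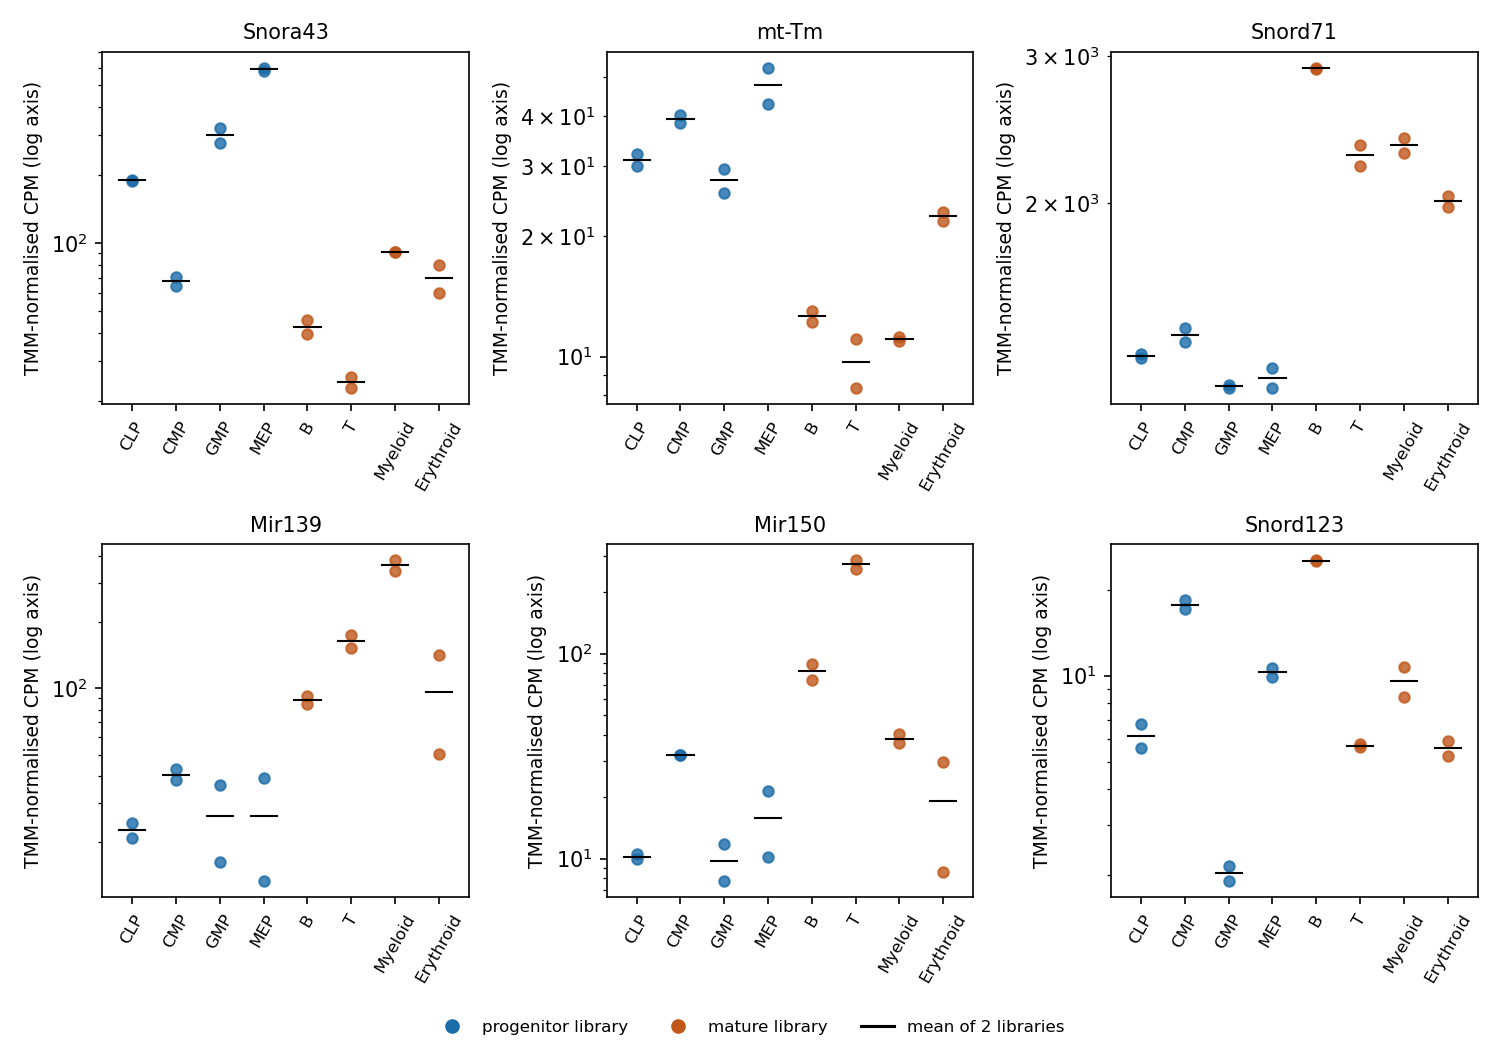
TMM-scaled CPM (vertical axes, log scale) of 6 named features in the 8 populations (horizontal axis). Points are libraries and lines are means of 2; Snora43 is highest in MEP, Snord71 is higher in each mature population than in each progenitor, and Mir139 is highest in Myeloid.

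Spliceosomal snRNAs were higher in progenitors as a list, with 47 of 117 tested members higher and 1 lower (47 and 1 adjusted over the list alone), a median of 0.53 and a camera adjusted p of 8.66e-06 (adjusted p = 0.00557 with an estimated correlation). By branch the list passed for CLP against B and T (adjusted p = 1.47e-12) and not for GMP against Myeloid (0.0814) or MEP against Erythroid (0.777). Against the other 7 populations, snRNA intervals higher and lower were 0 and 65 in T, 6 and 34 in B and 13 and 16 in CMP. They were 21 and 1 in Myeloid, 14 and 1 in Erythroid, 27 and 1 in CLP, 38 and 0 in GMP and 25 and 8 in MEP. The snRNA share of counts was 0.404% in progenitors and 0.325% in mature cells (exact permutation p = 0.343), and was highest in Myeloid at 0.490%. Gm24830, which has 17 similar annotated copies, had 8.33 ± 1.55 CPM in CLP and 1.93 to 2.19 in the mature cells. No other list passed the camera test here. By fry, H/ACA, Gas5, rRNA-processing and housekeeping also passed upward (adjusted p = 0.0168, 0.0146, 0.0143 and 0.0146). Snhg1 and Rpl13a passed downward by fry (adjusted p = 0.0146 and 0.0143). Of 20 rRNA-processing snoRNAs 8 were higher and 1 lower (8 and 1 adjusted over the list alone). U3 (Rnu3a, ENSMUSG00000065870) rose by 0.43 ± 0.070 and U13 (Snord13) by 0.22 ± 0.061, while U8 (Snord118), needed for large-subunit rRNA processing, fell by 0.45 on the log2 scale. C/D snoRNAs divided into 57 higher and 65 lower of 167 (59 and 68 adjusted over the list alone), and H/ACA snoRNAs into 24 and 18 of 111 (22 and 17). Counts higher and lower were 2 and 3 of 8 for snoRNAs hosted by Snhg1, 1 and 2 of 4 for Rpl13a, and 16 and 15 of 48 for other ribosomal protein genes, and each of these lists had the same or nearly the same count adjusted over the list alone (2 and 3, 1 and 2, 16 and 17). In the last list the median was 0.01 and the mean 0.03, while camera's direction was down (adjusted p = 0.483). Both scaRNAs fell, Scarna10 by 0.56 and Scarna9 by 0.48 on the log2 scale. Of 7 housekeeping RNAs, 7SK (Rn7sk) rose by 0.53 ± 0.049, the Y RNA Rny3 rose by 0.56 ± 0.13, and Rn7s1, a signal recognition particle RNA, fell by 0.29 on the log2 scale. The rest were Rny1 (0.13), Rn7s2 (-0.08), telomerase RNA Terc (0.46) and Vaultrc5 (-0.01). Among 14 tested marker miRNAs Mir99a rose by 0.97 ± 0.23 and Mir144 by 1.29 ± 0.40, Mir155, Mir181a-2 and Mir181a-1 fell by 0.62, 0.94 and 0.85, and Mir223, a miRNA of the myeloid lineage, was at -0.43 (adjusted p = 0.0515 by edgeR). The others were Mir125a (-1.24), Mir181b-2 (-0.23), Mir126a (0.29), Mir181b-1 (-0.19) and Mir125b-1 (0.23). Counts for the markers were 3 higher and 5 lower (3 and 6 adjusted over the list alone).

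SnoRNAs of 1 host gene moved in different directions. In Gas5, 6 of 10 snoRNAs were higher in progenitors and 3 lower (6 and 3 adjusted over the list alone). Snord78 rose by 0.64 ± 0.053 and the Snord80 interval ENSMUSG00000105780, which has 1 similar copy, fell by 0.51 (SE 0.041). The Snord80 interval ENSMUSG00000065735, also with 1 similar copy, rose by 0.20 ± 0.035, so calls for Snord80 went both ways. With library totals Snord78 was at 0.87 and these Snord80 intervals at -0.28 and 0.43. The other 2 lower members, Gm22489 and Gm26224, moved from -0.27 and -0.11 to -0.04 and 0.12. The Gas5 fall under library totals thus rests on an interval with a similar copy. In Gnl3 Gm24916 rose by 0.82 ± 0.043 and Snord69 fell by 0.64 (SE 0.037). In Nop56 Gm23187 rose by 0.85 ± 0.050 and Snord57 fell by 0.61 (SE 0.021). In Eif4a2 Gm24201 rose by 1.07 ± 0.17 and Snord2 fell by 0.78 (SE 0.034). With TMM 24 of 53 hosts with at least 2 tested snoRNAs had both a rise and a fall, and 14 had both under each of TMM, RLE and library totals. With populations as units the number was 0 by edgeR, and 5 at an unadjusted p under 0.05.

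**Figure D4:**
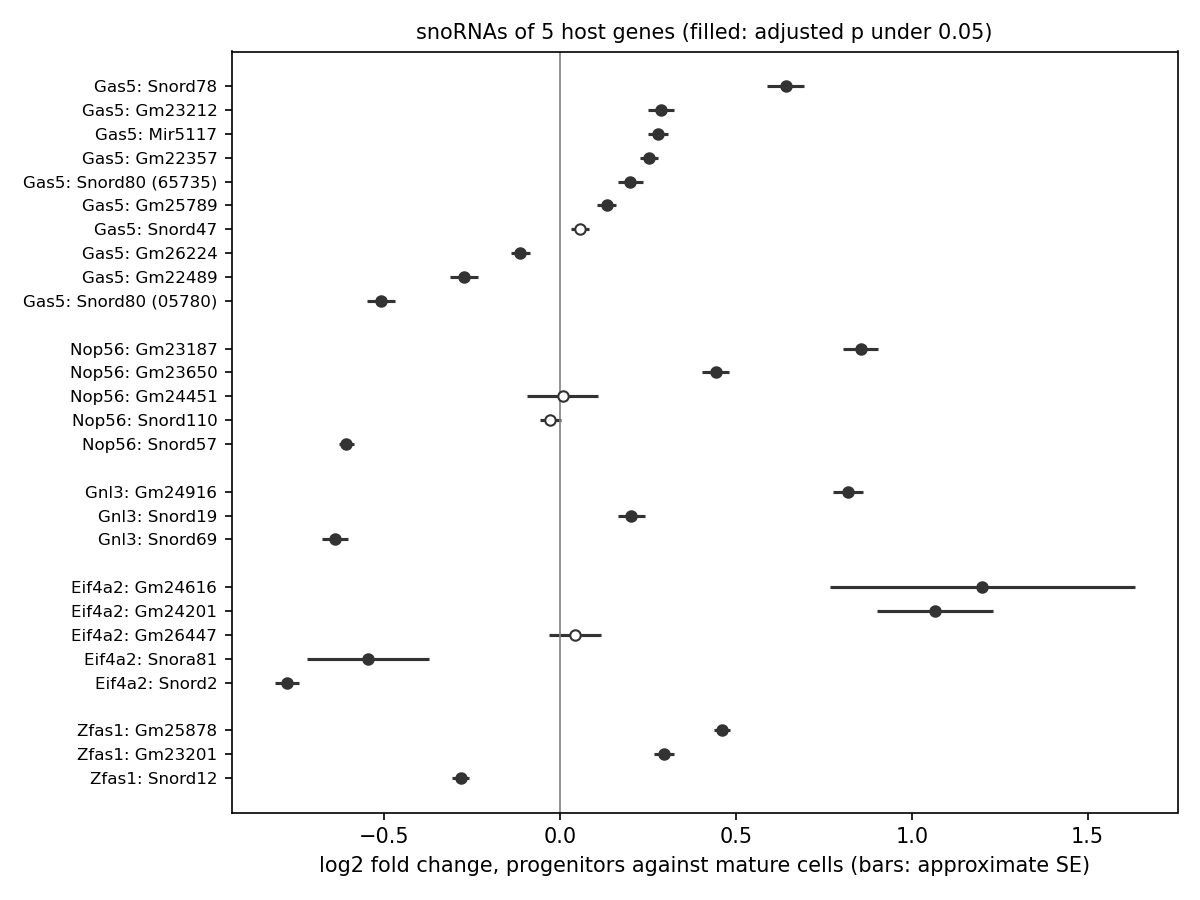
Log2 fold change between progenitors and mature cells (horizontal axis) of each tested snoRNA of 5 host genes (vertical axis), with TMM. Bars are approximate SE and filled points passed the threshold; each host has filled points on both sides of 0, and with library totals Gm26224 of Gas5 moves above 0.

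The stage result describes these 8 populations. With the libraries of each population summed and 4 populations set against 4, 21 features passed, 10 higher (among them Snora43, mt-Tm, mt-Tc, Gm24313 and Gm24830) and 11 lower (among them Mir139, Mir142, Mir22, Mir147 and Snord71), while 14 of the 20 rises and falls named above did not pass. These were Mir150 (adjusted p = 0.0597), Mir340 (0.0605), Mir532 (0.0614), Mir342 and Mir146 (both 0.0661) and Mir16-2 (0.0753) among the falls, and mt-Tg and n-TStga1 (both 0.0614), Gm44456 (0.0738), Gm25202 and Gm25813 (both 0.129), Gm27656 (0.146), Gm27773 (0.149) and Mir451a/Mir451b (0.479) among the rises. Of the mitochondrial tRNAs only mt-Tm and mt-Tc passed in this fit. With library totals in place of TMM the median of all features moved up by 0.231 and the split was 309 higher and 107 lower.

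In the lymphoid branch, 189 features were higher in CLP than in B and T and 135 lower. Spliceosomal snRNAs were higher as a list, with 62 of 117 higher and none lower (70 and 0 adjusted over the list alone), a median of 1.35 and a camera adjusted p of 1.47e-12 (adjusted p = 0.00013 with an estimated correlation). Rnu1b1, a U1 gene, rose by 1.49 ± 0.13, Rnu11, of the minor spliceosome, by 1.26 ± 0.21 and Rnu2-10, a U2 gene, by 0.28 ± 0.071, while Rnu12 was at 0.16 (adjusted p = 0.113 by edgeR). Mir451a/Mir451b was higher in CLP by 2.67 ± 0.23 and Snora43 by 2.56 ± 0.11, and Gm27656, Gm27773 and Gm25202 by 1.99, 1.98 and 1.89. Mir150 was lower by 3.87 on the log2 scale or 14.6-fold (SE 0.49, adjusted p = 5.47e-05 by edgeR), and Mir139 fell by 2.41, Mir532 by 2.31, Mir342 by 2.19 and the H/ACA snoRNA Gm25291 by 2.17. Markers had 2 higher and 5 lower of 14 (2 and 5 adjusted over the list alone). C/D snoRNAs, 56 higher and 70 lower of 167 (57 and 73 adjusted over the list alone), passed camera downward (adjusted p = 0.0195), but not with an estimated correlation (adjusted p = 0.820), nor without any of CLP library 2, CMP library 1, GMP library 1 or 2, MEP library 2, B library 2, T library 1, Myeloid library 1 or Erythroid library 1 (adjusted p 0.0592 to 0.292). It also did not pass with library totals, no low-count filter, the 10 CPM filter, snoRNAs and scaRNAs alone, similar copies or overlaps left out or CMP libraries summed, and over its 28 alternatives the adjusted p ran from 2.46e-06 to 0.820. Counts higher and lower were 18 and 16 for H/ACA, 5 and 9 for rRNA-processing, 6 and 3 for Gas5, 4 and 2 for Snhg1, 1 and 2 for Rpl13a, 16 and 15 for other ribosomal protein hosts and 2 and 0 for housekeeping RNAs (Rn7sk, 0.73, and Rny3, 0.81). The H/ACA median was 0.08 and the mean 0.15, with camera's direction down (adjusted p = 0.545), and for other ribosomal protein hosts the mean of 0.02 and camera's direction also differed. Without CLP library 1 the count was 196, and Mir532 (adjusted p = 0.0611) and Mir342 (adjusted p = 0.0768) did not pass. With library totals the median moved up by 0.449 and the split was 312 and 59; with snoRNAs and scaRNAs alone it was 80 and 98.

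In the granulocyte-monocyte branch, 122 features were higher in GMP than in Myeloid and 116 lower. The rRNA-processing snoRNAs were mostly higher in GMP, with 14 of 20 higher and 1 lower (15 and 1 adjusted over the list alone), a median of 0.85 and a camera adjusted p of 3.56e-05, which was lost with an estimated correlation (adjusted p = 0.239). U3 intervals rose, such as Rnu3a (ENSMUSG00000065870, 0.82 ± 0.14) and Rnu3b2 (ENSMUSG00000098925, 1.00 ± 0.18), as did Snora73a (U17, 0.88 ± 0.16), Snord14a (U14, 0.82 ± 0.16) and Snord13 (0.65 ± 0.12), and U8 (Snord118) fell by 0.99 on the log2 scale. The 10 U3 intervals lie at 5 positions in overlapping pairs, and the call was lost when features with similar copies or overlaps were left out (adjusted p = 0.124). Snora43 rose by 1.72 ± 0.14, Gm27773 by 1.71, Gm26387 by 1.58, Gm25106 by 1.37 and mt-Tm by 1.32 ± 0.16. Mir139 fell by 3.78 on the log2 scale (SE 0.58, adjusted p = 0.000782 by edgeR), Mir22 by 2.86, Mir340 by 2.57, Mir103-2 by 2.33 and Snord123 by 2.23 (SE 0.19), and the marker Mir223 fell by 1.41 (SE 0.34). The miRNA share differed 2.26-fold between the GMP libraries, and Mir139, Mir22, Mir340 and Mir103-2 fell by 3.35, 2.24, 2.05 and 1.89 without GMP library 1 and by 4.40, 4.03, 3.40 and 2.96 without GMP library 2. Other snoRNAs hosted in ribosomal protein genes, 13 higher and 0 lower of 48 (12 and 0 adjusted over the list alone), passed camera (adjusted p = 0.0447) but not with an estimated correlation (adjusted p = 0.856), nor without GMP library 1 (adjusted p = 0.637) or any of CLP library 1, B library 1 or T library 2 (0.0515 to 0.0659). It also did not pass with library totals, the 10 CPM filter, DESeq2, snoRNAs and scaRNAs alone, halved counts, miRNAs left out or similar copies or overlaps left out, and over its 28 alternatives the adjusted p ran from 0.000303 to 0.966. Counts higher and lower were 53 and 30 for C/D, 12 and 5 for H/ACA, 5 and 2 for Gas5, 2 and 3 for Snhg1, 0 and 0 for Rpl13a, 18 and 8 for spliceosomal snRNAs, 1 and 2 for housekeeping RNAs and 1 and 3 for markers. The count of features was 137 without Myeloid library 1, 142 without Myeloid library 2 and 144 without GMP library 1.

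In the erythroid branch, 74 features passed, 41 higher in MEP than in Erythroid and 33 lower. No library of MEP or Erythroid had its own replicate as the nearest library, and Mir451a/Mir451b was at 0.05 in this comparison. Snora43 rose by 3.08 ± 0.15, or 8.43-fold (adjusted p = 2.74e-07 by edgeR). The 5S rRNA intervals Gm47276 and Gm47281 both rose by 1.11, U13 (Snord13) by 1.10 ± 0.12 and mt-Tm by 1.10 ± 0.16. Mir142b fell by 1.68 on the log2 scale (SE 0.47, adjusted p = 0.0432 by edgeR), the signal recognition particle RNAs Rn7s1 and Rn7s2 fell by 1.10 and 0.82, and the related H/ACA snoRNAs Gm25291 and Gm25117 fell by 0.98 and 0.87. No list passed camera, while by fry the Rpl13a list passed upward (adjusted p = 0.00163) and housekeeping RNAs downward (adjusted p = 0.0151). Counts higher and lower were 21 and 15 for C/D, 6 and 4 for H/ACA, 1 and 0 for rRNA-processing, 0 and 1 for Gas5, 2 and 1 for Snhg1, 2 and 0 for Rpl13a, 1 and 4 for other ribosomal protein hosts, 5 and 3 for spliceosomal snRNAs, 0 and 2 for housekeeping RNAs and 0 and 0 for markers. For other ribosomal protein hosts the median was 0.03 while the mean and camera pointed down. The count fell to 30 without MEP library 2 and to 37 to 49 without any of CLP library 1 or 2, CMP library 1, B library 2, T library 1, Myeloid library 1, or Erythroid library 1 or 2. Mir142b did not pass in 11 of 16 such fits (adjusted p 0.0539 to 0.266; either library of CLP, B, T or Myeloid, or library 2 of CMP, MEP or Erythroid), nor with the replicate block (0.0683) or library totals (0.0554). It was at -2.41 without MEP library 1 and -0.98 without Erythroid library 2. Nor did Rn7s1 pass without MEP library 2 or Erythroid library 1 (adjusted p = 0.0520 and 0.0567). The split was 69 and 29 with library totals, 19 and 20 with RLE, and 30 and 37 with snoRNAs and scaRNAs alone.

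CMP had 110 features higher and 127 lower than the mean of GMP and MEP, the progenitors that arise from it. Spliceosomal snRNAs were lower as a list in CMP, with 28 of 117 lower and 7 higher (28 and 7 adjusted over the list alone), a median of -0.56 and a camera adjusted p of 0.00158 (adjusted p = 0.00692 with an estimated correlation). That call was lost with miRNAs left out (adjusted p = 0.224) and with similar copies or overlaps left out (adjusted p = 0.161). Among the snoRNAs of Snhg1, 6 of 8 were lower and 1 higher (6 and 1 adjusted over the list alone), such as Gm22744, which fell by 0.60 (SE 0.062). Snora43 fell by 2.64 on the log2 scale (SE 0.14, adjusted p = 1.46e-07 by edgeR), Snord17 by 2.48, U13 (Snord13) by 1.81, and the snRNA intervals Gm23744 and Gm25106 by 1.74 and 1.67. Snord123, within Snhg18 (chromosome 15, 32241853 to 32241923), rose by 1.95 ± 0.14, Mir222 by 1.94 ± 0.40, Gm47276 and Gm47281 by 1.94 and 1.91, and Mirlet7d by 1.66 ± 0.46, and the marker Mir99a, a miRNA of early progenitors, rose by 1.86 ± 0.37. Camera also called downward the C/D snoRNAs (37 higher, 64 lower, adjusted p = 0.0179), and those hosted by Snhg1 (adjusted p = 0.0179), by other ribosomal protein genes (5 and 21, adjusted p = 0.0179) and by Rpl13a (0 and 3, adjusted p = 0.0225), and the rRNA-processing snoRNAs (1 and 7, adjusted p = 0.0209). None of these 5 passed with an estimated correlation (adjusted p = 0.665, 0.497, 0.528, 0.497 and 0.497, in that order). The C/D call was also lost without library 1 of CLP, CMP, GMP or B, MEP library 2 or T library 2 (adjusted p 0.0546 to 0.0932), the Rpl13a call without those of CLP, CMP, GMP, MEP and T just named, T library 1, B library 2, Myeloid library 1 or Erythroid library 1 (0.0549 to 0.105), and the call for other ribosomal protein hosts without GMP library 1 (0.0639). None of the 5 passed with RLE, library totals, DESeq2, snoRNAs and scaRNAs alone, miRNAs left out or CMP libraries summed, and with the 10 CPM filter only that for other ribosomal protein hosts did. The Rpl13a call was also lost with similar copies or overlaps left out. Over 28 alternatives each, the adjusted p reached 0.825 (C/D), 0.528 (other ribosomal protein hosts) and 0.497 (Snhg1, rRNA-processing and Rpl13a), from lowest values of 0.000582, 0.000274, 0.000690, 0.000274 and 0.00175 in that order. Counts were 10 and 20 for H/ACA, 3 and 4 for Gas5, 2 and 0 for housekeeping RNAs and 4 and 1 for markers. The number of features was 104 without CMP library 1 and 132 without CMP library 2, and Mirlet7d passed in neither (adjusted p = 0.0748 and 0.0690), nor with the CMP libraries summed (0.0588). Snord17 fell by 1.85 without MEP library 2. With library totals the median moved up by 0.144 and the split was 146 and 97.

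GMP and MEP differed in 57 features, 29 higher in GMP and 28 lower. 7SK RNA (Rn7sk, chromosome 9, 78175303 to 78175633), which restrains transcription elongation, was higher in GMP by 1.22 ± 0.098, at 157 ± 19.0 CPM against 67.2 ± 0.856 in MEP (adjusted p = 1.28e-05 by edgeR). Gm23734, classed as a C/D snoRNA by its boxes and within Mgat5, was higher by 1.15, the snRNA intervals Gm23744 and Gm25106 by 1.11 and 1.08, and the Snord80 interval ENSMUSG00000105780 by 0.70. Snord123 fell by 2.33 on the log2 scale (SE 0.19), with 2.03 ± 0.177 CPM in GMP and 10.3 ± 0.496 in MEP, Gm47276 and Gm47281 fell by 2.01 and 1.91, Snora43 by 0.97 and mt-Tm by 0.79. Of 4 snoRNAs hosted by Rpl13a 3 were lower in GMP (4 adjusted over the list alone), with Snord34 at -0.69 ± 0.055, and camera's adjusted p was 2.65e-05, lost with an estimated correlation (adjusted p = 0.0967). Counts higher and lower were 16 and 21 for C/D, 2 and 2 for H/ACA, 0 and 1 for rRNA-processing, 2 and 3 for Gas5, 1 and 1 for Snhg1, 5 and 1 for other ribosomal protein hosts, 8 and 0 for spliceosomal snRNAs, 1 and 0 for housekeeping RNAs and 0 and 0 for markers. Median and mean differed in sign for H/ACA (0.07 and -0.04) and for markers (0.18 and -0.10), and neither list passed. The count was 21 to 30 without any of CLP library 1 or 2, CMP library 1, GMP library 1, MEP library 2, B library 2, T library 1 or 2, Myeloid library 1 or Erythroid library 1, and mt-Tm did not pass without GMP library 1 or MEP library 2 (adjusted p = 0.0712 and 0.105), nor with no low-count filter (0.103). The split was 52 and 27 with library totals and 8 and 12 with RLE.

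B cells had 140 features higher and 71 lower than T cells. Snord17 (chromosome 2, 144265979 to 144266216), within Snx5, fell by 3.85 on the log2 scale (SE 0.53, adjusted p = 0.000263 by edgeR), with 185 ± 9.97 CPM in B and 2670 ± 310 in T. Snord64, from the imprinted Snrpn-Ube3a locus, fell by 4.13 (SE 0.49, adjusted p = 9.21e-05 by edgeR), with 0.472 ± 0.00363 TMM-scaled CPM in B and 8.38 ± 0.343 in T, and it was the only tested snoRNA of 13 listed from that locus. Its values in the other 6 comparisons did not pass (-0.99 to 0.88). Mir30a, Mir24-1, Mir16-2 and Mir148a fell by 2.55, 2.24, 2.03 and 2.01, and the markers Mir150, Mir451a/Mir451b, Mir223 and Mir155 by 1.74, 1.44, 1.14 and 1.08. Snord123 rose by 2.15 ± 0.18, the U5 gene Rnu5g by 1.27 ± 0.088, and the snRNA intervals Gm23143 and Gm25099 by 1.54 and 1.36. SnoRNAs of Gas5 were higher in B, 7 of 10 with none lower (8 and 0 adjusted over the list alone), led by Snord78 (1.26 ± 0.11) and Gm23212 (0.92 ± 0.074), with a camera adjusted p of 0.00112, lost with an estimated correlation (adjusted p = 0.645). Camera also called C/D snoRNAs upward (65 and 25, adjusted p = 0.00988), spliceosomal snRNAs upward (27 and 1, adjusted p = 0.0218) and markers downward (0 and 4, adjusted p = 0.00703). None of these 3 passed with an estimated correlation (adjusted p = 0.722, 0.115 and 0.722). By fry the marker list did not pass (adjusted p = 0.108). H/ACA, housekeeping and Rpl13a (each 0.0375) and other ribosomal protein hosts (0.00596) passed upward by fry. The C/D call was also lost without B library 1 (adjusted p = 0.215), and the snRNA call without B library 2, CMP library 1, GMP library 1, Myeloid library 1 or T library 1 or 2 (adjusted p 0.0507 to 0.0965). The C/D call was lost too with the 10 CPM filter, snoRNAs and scaRNAs alone or miRNAs left out, the Gas5 call with the last 2 of these, the marker call with similar copies or overlaps left out, and the snRNA call with no low-count filter, miRNAs left out, similar copies or overlaps left out or CMP libraries summed. Over their alternatives the adjusted p reached 0.823, 0.645, 0.722 and 0.454 in that order. Counts were 10 and 1 for H/ACA, 5 and 0 for rRNA-processing, 3 and 2 for Snhg1, 0 and 0 for Rpl13a, 19 and 5 for other ribosomal protein hosts and 1 and 0 for housekeeping RNAs (Rn7sk, 0.98). The number of features was 120 without B library 1, 138 without B library 2 and 120 without T library 2, and Mir16-2 and Mir148a passed in none of these (adjusted p 0.0584 to 0.0965), nor Mir24-1 without B library 1 (adjusted p = 0.0795). With snoRNAs and scaRNAs alone the split was 54 and 63.

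Against the mean of the other 7 populations, T differed most, with 137 features higher and 221 lower. Features enriched in both libraries over all others, of which chance gives 0.833% if single libraries are exchanged and 12.5% if the libraries of a population always lie together, more than any count here, numbered 63 in T, 66 in Myeloid, 62 in CMP, 35 in B, 33 in GMP, 30 in MEP, 10 in CLP and 9 in Erythroid. In MEP Snora43 stood out, with 14492 and 9248 counts and a pooled level 4.90 times that of the other 14 libraries (95% counting interval 4.79 to 5.02). In CLP the H/ACA snoRNA Snora31 stood at 2.87 times (2.62 to 3.15), Gm24888 at 2.25 and mt-Ti at 1.97. In T Mir592 stood at 18.3 times (12.9 to 26.2), Mir183 at 10.8 and Mir211 at 45.8 (15.3 to 184, from 24 and 16 counts). In Myeloid Mir147 stood at 9.78 times (7.79 to 12.3), Mir135a-2 at 9.29 and Mir365-2 at 11.5. In CMP Mir6236 stood at 19.2 times, Gm25162 at 14.8 and Mir199a-2 at 14.2, each from at most 46 counts in a library. In B Gm44341 stood at 3.19, Gm47311 at 3.16 and Mir10b at 2.89, in GMP Gm25211, Gm26035 and Gm23057 at 4.29, 3.27 and 2.19, and in MEP Gm22692 at 6.26 and Gm27399 at 2.47. In Erythroid Mir467a-7, Gm25547 and Gm25583 stood at 3.36, 2.95 and 2.88, from 10 to 24 counts in a library. Features higher and lower were 131 and 109 in CMP, 115 and 120 in B, 141 and 84 in Myeloid, 143 and 52 in GMP, 150 and 63 in MEP, 96 and 82 in CLP and 83 and 41 in Erythroid. With library totals the median moved by 0.157 in CLP, 0.233 in CMP, -0.316 in B, -0.393 in T and 0.209 in Myeloid, and the splits were 156 and 44, 221 and 72, 49 and 234, 72 and 304, and 237 and 36. With RLE the median moved by 0.116 in B, 0.135 in T and -0.123 in Myeloid, and splits that moved by over 10 points were 102 and 45 in CLP, 86 and 55 in GMP, 167 and 171 in T and 110 and 102 in Myeloid. With snoRNAs and scaRNAs alone such splits were 71 and 89 in CMP, 71 and 62 in GMP, 74 and 75 in MEP, 78 and 53 in B, 96 and 80 in T and 64 and 50 in Erythroid. Leaving out 1 library of the population itself moved the count to 51 and 62 in CLP, 115 and 132 in CMP, 139 and 114 in B, 97 and 108 in Myeloid, 118 in GMP (library 1), 95 in MEP (library 2) and 50 in Erythroid (library 1). Leaving out CLP library 1 gave 136 in MEP, and leaving out CMP library 1 gave 79 in Erythroid. Of the enriched features, Gm24888 did not pass without either CLP library (adjusted p = 0.111 and 0.0851), mt-Ti without CLP library 1 (0.0610), Mir199a-2 without CMP library 2 (0.0686), Gm25211 without GMP library 2 (0.0596), Gm22692 without MEP library 1 (0.0871), Mir365-2 without Myeloid library 2 (0.0602) or Gm25547 without Erythroid library 1 (0.210). Gm26035 did not pass without CLP library 1 or either GMP library (0.0536 to 0.114), Gm25583 without either Erythroid library (0.0732 and 0.145), or Mir467a-7 without any of 11 libraries, those of MEP and B and CLP library 2 being the exceptions (0.0532 to 0.212), or with the replicate block (0.0564) or CMP libraries summed (0.0611). With DESeq2 Gm22692 did not pass.

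The step from progenitor to mature cell was compared between branches. Features higher in the progenitor of all 3 branches numbered 18, and 8 were lower in all 3, where independent steps would give 1.69 and 0.921. That expectation takes every feature as equally likely to be called. It cannot tell a shared change from calls that follow abundance. Those higher included Snora43, mt-Tm, mt-Tc, mt-Rnr2, Snord70, Snord13 and Gm24313, and those lower included Snord71 (-0.97, -0.96 and -0.70 in the lymphoid, granulocyte-monocyte and erythroid branch), Snord69 (-0.78, -0.82 and -0.68), Mir147 and Mir142b. Of these, Snord70, Snord13, mt-Rnr2 and Snord69 did not pass with populations as units (adjusted p = 0.216, 0.698, 0.121 and 0.121 by edgeR), and the others did. Among the features of all 3 branches not named here, only Gm24830 and Gm26340 passed in that fit (adjusted p = 0.0167 and 0.0374 by edgeR). Those that did not included Snord82 (0.587), Gm25894 (0.544) and Snord37 (0.129). The call of Mir142b in the erythroid branch was often lost on leaving out 1 library, as given above. The steps of 134 features differed between the lymphoid and granulocyte-monocyte branches, of 160 between the lymphoid and erythroid branches and of 69 between the granulocyte-monocyte and erythroid branches, and leaving out 1 library gave 54 to 149, 91 to 165 and 22 to 94. Gm25117, an abundant H/ACA snoRNA within Nap1l1, changed by -1.87 from B and T to CLP and by 0.20 from Myeloid to GMP, a difference of -2.07 ± 0.14 (adjusted p = 3.28e-06 by edgeR). Snord123 was lower in GMP than in Myeloid and higher in MEP than in Erythroid, a difference of -3.11 ± 0.25 (adjusted p = 7.28e-05 by edgeR).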

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

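The tests of a difference between branches were chosen before the data were examined. Chosen only after the results were seen were the fits of Snord17 with similar copies or overlaps left out and with the CMP libraries summed.

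The step from mature cell to progenitor differed between branches, by a test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), for 134 features between the lymphoid and granulocyte-monocyte branches, for 160 between the lymphoid and erythroid branches and for 69 between the granulocyte-monocyte and erythroid branches. With library totals in place of TMM the median difference moved by 0.543, 0.389 and -0.155, and the splits, 68 and 66, 89 and 71, and 42 and 27 with TMM, were 242 and 22, 186 and 30, and 29 and 62. With snoRNAs and scaRNAs alone the split between the lymphoid and erythroid steps was 54 and 75. The first count was 54 to 85 without any of CLP library 1 or 2, CMP library 1, B library 2 or Myeloid library 1, the second was 91 and 95 without CLP library 1 and 2, and the third was 22 to 41 without any of CLP library 1 or 2, CMP library 1, B library 2, T library 1 or 2, Myeloid library 1 or Erythroid library 1.

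Between the lymphoid and granulocyte-monocyte steps Gm25291 differed by -2.31, its relative Gm25117 by -2.07 and Snord17 by -2.15. The Snord17 difference (adjusted p = 0.0387) did not pass in 10 of the 16 fits that left out 1 library, which were either library of CLP, CMP, B or Myeloid, GMP library 2 and T library 1 (adjusted p 0.0575 to 0.160). Nor did it pass with the replicate block (0.0547), library totals (0.0712), features with similar copies or overlaps left out (0.0529) or CMP libraries summed to 1 (0.0623). Between the lymphoid and erythroid steps Mir150 differed by -3.60 (-4.74 to -2.91 without MEP library 1 or either Erythroid library), with steps of -3.87 and -0.27, Mir451a/Mir451b differed by 2.62, with steps of 2.67 and 0.05, and Gm25106 differed by 2.39. Between the granulocyte-monocyte and erythroid steps Snord123 differed by -3.11, with steps of -2.23 and 0.88, and the snRNA intervals Gm25106 and Gm23744 differed by 2.09 and 1.85, each higher in GMP than in Myeloid and lower in MEP than in Erythroid.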

How the results depend on the processing

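Alternatives chosen after seeing the data were halved counts, miRNAs left out, features with similar copies or overlaps left out, and both CMP libraries summed to 1. With DESeq2, halved counts, Erythroid and MEP out of the contrast, and the replicate block, each count in the report stayed within 1.5 times; with the replicate block progenitors against mature cells gave 365, while Mir142b, MEP against Erythroid, Mir467a-7, Erythroid against the other 7 populations, and the Snord17 difference between branches no longer passed (adjusted p = 0.0683, 0.0564 and 0.0547). Causes were not tested except where fewer features or libraries entered a fit. With 222 counts in all, no Dlk1-Gtl2 snoRNA passed the low-count filter over 16 libraries. The summed Dlk1-Gtl2 snoRNA abundance difference ran from 0.49 to 1.02 over other scales and did not pass in any; whether depth, the spread among progenitors (0.418 to 2.06 CPM) or the smallest p of 0.0286 limits it was not tested.

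For progenitors against mature cells the count was 21 with libraries of a population summed, 196 with stage alone over 16 libraries, 191 with snoRNAs and scaRNAs alone and 228 with similar copies or overlaps left out. With RLE size factors it was 39 for MEP against Erythroid, 20 for GMP against MEP, 75 for Erythroid against the other 7 populations and 28 for the granulocyte-monocyte step minus erythroid step. With library totals without TMM the lymphoid step minus granulocyte-monocyte step gave 264. With no low-count filter the counts were 49 for MEP against Erythroid, 29 for GMP against MEP, 78 for Erythroid against the other 7 populations and 99 for the lymphoid step minus erythroid step, and at least 10 CPM in at least 2 libraries gave 33 for GMP against MEP.

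With snoRNAs and scaRNAs alone, fewer features were tested, and the counts were 228 for features differing among the 8 populations, 178 for CLP against B and T, 122 for GMP against Myeloid, 149 for CMP against GMP and MEP, 117 for B against T, and 131, 176 and 109 for B, T and Myeloid against the other 7 populations. With similar copies or overlaps left out, fewer features were tested too, and they were 290 among the 8 populations, 192 for CLP against B and T, 149 for GMP against Myeloid, 42 for MEP against Erythroid, 145 for CMP against GMP and MEP, 17 for GMP against MEP and 117 for B against T. Against the other 7 populations they were 95 (CLP), 103 (GMP), 101 (MEP), 133 (B), 213 (T), 140 (Myeloid) and 63 (Erythroid), and for the branch differences 50, 82 and 43. With CMP libraries summed to 1, the counts were 106 for CMP against GMP and MEP, 113 for CMP and 81 for Erythroid against the other 7 populations, 40 for MEP against Erythroid, 21 for GMP against MEP, 82 for the lymphoid step minus granulocyte-monocyte step and 26 for the granulocyte-monocyte step minus erythroid step. With miRNAs left out they were 102 for GMP against MEP and 117 for the granulocyte-monocyte step minus erythroid step; the cause was not tested.

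The count of feature lists that passed, 16, was 3 with an estimated correlation, 2 with snoRNAs and scaRNAs alone, where fewer lists were tested, and 10 with similar copies or overlaps left out. The direction of the C/D snoRNAs reversed for CLP against B and T with library totals without TMM (adjusted p = 0.3022), for B against T with snoRNAs and scaRNAs alone (0.8226) and with miRNAs left out (0.06859), and for CMP against GMP and MEP with miRNAs left out (0.8246); the cause was not tested. Over all alternatives these adjusted p values ran from 2.46e-06 to 0.820, 4.74e-06 to 0.823 and 0.000582 to 0.825. By fry, further lists passed that camera did not call. For CLP against B and T, Gas5 and housekeeping passed upward (adjusted p = 0.0144 and 0.00999), Rpl13a passed downward (0.01865) and C/D did not pass (0.09585). Upward by fry were also snRNAs for GMP against Myeloid (0.00106) and housekeeping for CMP against GMP and MEP (0.00581). For GMP against MEP, snRNAs and housekeeping were (0.0029 and 0.0133).

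Leaving out 1 library in turn, with the lone library left assumed to vary like the other groups, gave 322 to 392 for progenitors against mature cells, 389 to 475 among the 8 populations, 196 to 347 for CLP against B and T, 137 to 252 for GMP against Myeloid, 30 to 81 for MEP against Erythroid, 104 to 251 for CMP against GMP and MEP, 21 to 65 for GMP against MEP and 120 to 232 for B against T. Against the other 7 populations it gave 51 to 190 (CLP), 115 to 260 (CMP), 118 to 192 (GMP), 95 to 211 (MEP), 114 to 240 (B), 252 to 380 (T), 97 to 265 (Myeloid) and 50 to 136 (Erythroid). For the branch differences it gave 54 to 149, 91 to 165 and 22 to 94. It gave 12 to 27 feature lists, with 26 without GMP library 2 and 27 without MEP library 1, and 0.58 to 0.77 for the summed Dlk1-Gtl2 snoRNA abundance difference.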

Other observations

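Chosen only after the results were seen were the tests of insert recovery and of myeloid RNA for the miRNA shares, of relatives, of background reads and of a common scaling factor for the snRNA intervals, and of host transcription and both tests of length for the snoRNA hosts. The test of host transcription set its bounds, and the tests of myeloid RNA parted GMP from MEP and Erythroid, on values already in view.

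The spliceosomal snRNA rise in CLP was in scarce and abundant intervals, with a greater median in the scarce ones. The 97 intervals with a mean of under 1000 counts had a median log2 change of 1.53 against B and T, with 49 higher and 0 lower, and the 20 abundant intervals had a median of 0.27, with 13 higher and 0 lower. Only 14 of the 97 had no similar annotated copy at 95% identity, and 7 of those 14 were higher. The others can share reads with their copies, so their calls are not independent. Summed, the scarce intervals had 591 ± 20.5 TMM-scaled CPM in GMP, 523 ± 1.89 in CLP, 496 ± 5.18 in MEP, 440 ± 32.6 in Erythroid, 396 ± 0.0151 in Myeloid, 344 ± 16.3 in CMP, 254 ± 0.230 in B and 192 ± 8.67 in T (n = 2 libraries each). Gm25360, an snRNA interval, had 113 ± 8.16 CPM in MEP, 94.9 ± 3.87 in CLP and 25 ± 0.161 in T.

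Reads spilling from an abundant relative at a fixed rate would move an interval with that relative, but 27 of 29 scarce intervals with one lay above it, by a median of 1.55. Background over all scarce intervals would raise others alike, but 127 H/ACA and unclassified intervals as scarce had a median of 0.107, while 20 mitochondrial tRNAs and 34 other small RNAs as scarce had 1.11 (11 higher, 0 lower) and 0.89 (11 and 1), and 227 miRNAs had -0.50, so a background of fragments outside the snoRNAs stays open. Library totals raise all features of this comparison alike, by 0.449 at the median, so their median of 1.977 decides nothing on normalization, but a factor common to a library would leave no gap between classes, and the scarce snRNAs lay 1.422 above those other intervals (SE 0.114 over resampled intervals). That SE takes the intervals as independent, although most of the scarce snRNA intervals have similar copies. Relatives, background over all scarce intervals and a common factor are each argued against as the whole cause. A candidate explanation left open is higher output of variant snRNA genes in CLP than in B and T, which nothing here separates from such a background or from differences in insert recovery between snRNAs and snoRNAs, which were not tested.

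The miRNA share differed 2.26-fold, 2.49-fold and 2.54-fold between the libraries of GMP, MEP and Erythroid, and 1.01-fold to 1.09-fold in the other 5 populations. If one library of a pair held more short inserts, nearly all miRNAs would be higher in it. Of 83 miRNAs 96.39%, 92.77% and 93.98% were higher in it in GMP, MEP and Erythroid. The lowest lay between the bounds set for either answer. Gm44456, Gm27656 and n-TSaga9, classed as miRNAs by gene type, were lower in all these pairs. Whether they belong in that class was not tested, so more short inserts in one library stay open. RNA of mature myeloid cells in one GMP library would move other features toward the Myeloid level, but the median move was 0.0746 of the distance (median absolute deviation 0.185, 18 features) where a share of 0.38 was needed, which argues against it as the whole cause; Mir223, abundant in Myeloid at 921 ± 36.4 CPM, was 424 and 268 in the GMP libraries. In MEP and Erythroid the moves were 0.209 (median absolute deviation 0.203, 37 features, 0.337 needed) and 0.299 (0.101, 15 features, 0.504 needed), past the bound of 0.2 set for this source in GMP and below the need by more than that spread in Erythroid alone; of 7 miRNAs scarcer in Myeloid than in the lower library 28.57% were higher in the other in each pair, among them Mir451a/Mir451b (124 to 181 CPM in MEP, 114 to 180 in Erythroid, 47 in Myeloid), so a part from this source cannot be told apart. No biological explanation was tested, since both libraries of a pair carry the same labels.

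Of 53 host genes 26.42% had a called rise and a called fall between progenitors and mature cells under TMM, RLE and library totals, which restates the pattern. With populations as units (edgeR) the count was 0, and 5 at an unadjusted p under 0.05. That fit bears on stage, not on whether snoRNAs of a host keep a fixed ratio over libraries, as host transcription alone requires. In Gnl3 Gm24916 was at 0.82 (SE 0.043) and Snord69 at -0.64 (SE 0.037). In Nop56 Gm23187 was at 0.85 (SE 0.050) and Snord57 at -0.61 (SE 0.021). Against the spread between libraries, the measured levels of these snoRNAs did not move together. The 14 hosts were picked by such calls, and no ratio between snoRNAs of a host was tested. Recovery by length, which stays open below, could also give opposite calls. Host transcription alone is therefore not decided in the 14 hosts or in the others. If shared reads were the cause, opposite calls would end where snoRNAs have no similar copy or overlap, but 31.43% of 35 such hosts had both. A first test of length gave a Spearman correlation within hosts of 0.1952 (SE 0.0744 over resampled hosts, 172 snoRNAs), which is not clear of its bound of 0.2, so recovery by length stays open. A second was then added: with a length trend removed from each library 49.06% of hosts had both. These were 26 hosts, all 14 of the earlier ones among them, against 24 with TMM alone. That fit was scaled to snoRNA totals without TMM, so the counts differ in scaling too. Removing the trend also centres changes near 0 at each length, which favours opposite calls. The count therefore does not decide on a smooth trend. No biological explanation other than host transcription was tested.

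For the count of 373 features between progenitors and mature cells, 2 of the 35 ways to part the 8 populations into 4 and 4 gave as many, the real one included, and the highest of the others was 396, for CLP, GMP, MEP and Erythroid against CMP, B, T and Myeloid, so chance cannot be excluded. In a fit with stage alone 1 of 100 drawn splits of the 16 libraries, the real one, gave as many as its 196, and the highest of the others was 183. Of those 100 splits only 4 kept all populations whole, with 196, 183, 0 and 0, and 95 of the other 96 gave 0, so this does not exclude chance among populations.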
